A study of Mus musculus with 3 samples.

How the data were processed

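RNA from mouse primordial germ cells (PGC), spermatogonia (SPG) and whole adult testis was compared with RNA from embryos whose gonads had been removed, on 2-colour spotted arrays. Per the labels' protocols, the mice were of the CD-1 strain, the PGCs were taken at 13.5 days postcoitum and pulled down on magnetic beads against CD15, and the SPGs were taken at 8.5 days after birth and enriched by letting somatic cells settle and adhere in a short culture. Per the labels, the purity of the PGCs was judged by alkaline phosphatase staining, and that of the SPGs by the presence of Stra8 and the absence of Fn1. The gonad-less embryos were of 13.5 days postcoitum and served as the control in every comparison. Amplified RNA was labelled with Cy3 or Cy5, per the labels' protocols.

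The deposited table holds 1 column per sample and 38880 spots, with no missing values. Per the file headers of the array list, each sample was hybridised on 2 arrays of opposite dye orientation, 6 arrays in all, and each deposited log2 ratio column is therefore taken as the result of 1 dye-swap pair. How the pair was combined, the background correction and the normalization within arrays are not given in the sources used here. The submitters' processing notes name limma, with no version. The values run to both sides of 0, and the mean of each column over all spots is 0, as in columns centred on the mean; their medians are 0.05 in PGC, 0.00 in SPG and -0.02 in adult testis, and their SDs are not equalised. The base of the logarithm is not stated in the deposited table and was taken as log2 because limma writes log ratios in base 2. The direction of the ratio is not stated either. It is likely sample over gonad-less embryo, because the labels name the embryo RNA as the control to which the 3 samples were compared, and all values are read in that direction; with the opposite direction, higher and lower would change places throughout.

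The files name each spot by its position only, as 3 numbers: a block (48 of them), a second number (27 values) and, last, a number of 30 values that is called the row here. No table used here pairs these positions with genes. The 22 gene lists, the genes to be named, the comparison of X-linked with autosomal genes and the spread between probes of one gene, all fixed before the data were examined, were therefore not analysed here, and the unit of every count is a spot. Control spots could not be left out by name, so all spots enter each count. In place of named genes, the 2 highest and 2 lowest spots of each comparison are given; the planned rule was 5 genes at each end.

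Each group is 1 sample with 1 column, so there is no replicate, no test was run and no p-value or standard error is given. The number of arrays limits the precision, and the spread between animals or cell isolations is not in the table. The only measure of spread is technical: the SD over the 1296 spots of row 30, which hold values close to 0, was 0.12 in PGC, 0.11 in SPG and 0.15 in adult testis. These spots were chosen after the data were examined. With almost no ratio beyond 1 they look like blank or control spots, and spots with signal may scatter more, in which case the simulated values that use this SD are too low. Spots at a log2 ratio of 1 or more, or of -1 or less (2-fold either way if the base is 2), were counted in the 3 comparisons with gonad-less embryo. They were also counted in the 3 differences between samples. The common reference cancels in these differences as deposited, but not once the columns are scaled by unequal factors. These counts describe the arrays and are not counts of differentially expressed genes.

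Overlaps of spots between samples are given beside the number 2 independent lists of the same sizes would share. Because the samples share 1 control, unchanged samples were also simulated against a common control, with equal variance from the sample and the control and the SD taken from the spots of row 30. The control's part was scaled to the SD of each column. It was therefore not of equal size in the columns and does not cancel in their differences. A second simulation took the SD from the central spread of each column, as the SD of a normal distribution with its median absolute deviation. For values read in another sample, as many of the most extreme simulated spots as the observed side holds were read in the same way. Correlations and covariances are across spots, which are not independent replicates, and their 95% intervals come from 1000 resamples of the 48 blocks. Each sample has 1 column against the common control, so the controls could not be split. The counting was tested on simulated data with 200 spots shifted by 2 in PGC and 200 by -2 in adult testis; the shift was far larger than the noise, so this checked the code and says nothing about how many true differences the threshold finds.

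The alternatives fixed before the data were examined were centring on the median, scaling the columns to an equal median absolute deviation, thresholds of 1.5 and 2, and correlations without the 1% of spots with the most extreme values in any sample. Centring on the median of each block, centring on the median of each row, and leaving out rows 1, 29 and 30 were added after the data were examined. Counting all probes rather than genes is what every count does here; the alternatives that need gene names were not run. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used, and figures were drawn with matplotlib 3.10.9.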

Results

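The study set fetal primordial germ cells (PGC), postnatal spermatogonia (SPG) and whole adult testis against a soma without gonads. PGCs are the precursors of the germ line, and SPGs are the mitotic germ cells of the young testis. Whole adult testis holds the germ cells of adult spermatogenesis and the somatic cells around them. There was 1 sample each of PGC, SPG and adult testis, and each was read on 2 arrays as a log2 ratio to gonad-less embryo RNA over 38880 spots. With 1 sample per group no difference could be set against a spread between replicates. Ratios are read as sample over gonad-less embryo, the likely direction. Spots are named by their 3 position numbers (block, second number and row), and their genes were not analysed here.

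In PGCs, 1754 spots had a ratio of 1 or more and 2377 a ratio of -1 or less, together 10.6% of all spots. The lower side also reached further: 188 spots lay at -3 or below and 67 at 3 or above. Of the 188, 36 lay in row 1, where an even spread over positions would place 6.27, and 152 elsewhere. None of the 67 lay in row 1. With the columns scaled to an equal spread (an equal median absolute deviation), PGC had 572 spots at -3 or below and 181 at 3 or above. It then had 2992 spots at 1 or more. The 2 highest spots in PGC, 43_5_16 and 19_15_11, had ratios of 5.85 and 5.68, and the 2 lowest, 8_26_23 and 19_27_23, had -5.87 and -5.73. Spot 43_5_16 was close to the embryo level in adult testis (0.06) and at 0.77 in SPG, whereas 19_15_11 was high in SPG (5.06) and adult testis (3.59) as well. Both low spots were also low in SPG (-4.45 and -4.18) and in adult testis (-5.96 and -6.03). The 1754 spots higher in PGC had a median of 0.91 in SPG and of 0.04 in adult testis. As many of the highest spots of a simulated unchanged PGC sample, sharing the control, had medians of 0.12 in SPG and 0.16 in adult testis with the noise of row 30, and of 0.27 and 0.49 with the central spread as noise. Of the 2377 spots lower in PGC, 56.1% were at -1 or below in SPG and 70.7% in adult testis, against 0% in both with the noise of row 30, and 0.04% and 9.97% with the central spread. The simulated noise was narrower than the values, whose SDs were 0.67 in PGC, 0.64 in SPG and 1.13 in adult testis. The simulated medians and shares follow from that assumed noise, so they cannot show how much a shared control contributes.

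In SPGs, both sides were nearly equal in number in the deposited values, with 2030 spots at 1 or more and 2033 at -1 or less, 10.5% of all spots. At 3 or above there were 59 spots, and at -3 or below 103. With the columns scaled to an equal spread these counts were 141 and 222. The 2 highest spots in SPG, 19_15_11 and 9_15_5, had ratios of 5.06 and 4.81, and the second of them was also high in PGC (3.09) and adult testis (2.75). The 2 lowest, 42_9_23 and 41_20_9, had -5.13 and -5.04 and lay between -4.97 and -4.21 in the other 2 samples. The spots higher in SPG had a median of 0.78 in PGC and of 0.08 in adult testis, where unchanged samples simulated with the central spread gave 0.22 and 0.48. Those lower in SPG had medians of -1.32 in PGC and -1.48 in adult testis, where the simulation gave -0.24 and -0.48. Here too the simulated medians scale with the assumed noise.

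As deposited, adult testis had more spots beyond 1 than either germ cell sample, an order that did not hold once the columns were scaled to an equal spread. In the deposited values 4226 spots lay at 1 or more and 4926 at -1 or less, 23.5% of all spots. Its high side reached furthest, with 1099 spots at 3 or above (8-fold if the base is 2) against 255 at -3 or below. With the columns scaled to an equal spread these counts were 237 and 21. The 2 highest spots in adult testis, 47_15_18 and 9_19_8, had ratios of 6.76 and 6.75, while in PGC they had 0.48 and 0.03 and in SPG -0.12 and 0.08. The 2 lowest, 19_27_23 and 8_26_23, were the 2 lowest of PGC in the other order. Of the 4226 spots higher in adult testis, 3109 (73.6%) were also at least 1 above both PGC and SPG, and the medians of these spots were 2.39 in adult testis, 0.07 in PGC and 0.03 in SPG. With the columns scaled to an equal spread, 1899 spots met this rule. On the low side, 2046 spots of 4926 (41.5%) were at least 1 below both germ cell samples. The testis values were more widely spread over all spots (SD 1.13) than those of PGC (0.67) and SPG (0.64). The equal spread used here is an equal median absolute deviation, which depends little on extreme spots and does not equalise the SDs. As deposited, it was 0.32 in adult testis, 0.15 in PGC and 0.17 in SPG. When the 3 columns were scaled to an equal spread, 2984 spots lay at 1 or more and 2590 at -1 or less in adult testis, fewer than the 2992 and 3526 in PGC, and the larger side of adult testis turned from low to high.

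**Figure D1:**
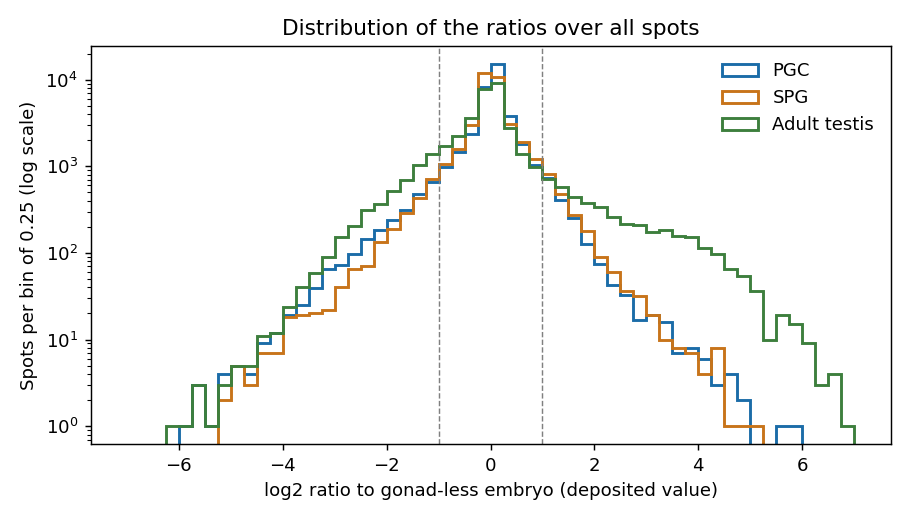
Number of spots (log scale) per bin of 0.25 in the log2 ratio to gonad-less embryo, for PGC, SPG and adult testis; the dashed lines mark ratios of -1 and 1. Adult testis has 1099 spots at 3 or above, against 67 in PGC and 59 in SPG, while on the low side at -3 or below the counts are 255, 188 and 103. With an equal median absolute deviation the counts would be 237, 181 and 141 high and 21, 572 and 222 low.

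The spots that were low against the embryo were shared between the samples to a greater extent than the spots that were high. All 3 samples were at -1 or less at 1046 spots, which is 44.0% of the low spots of PGC, 51.5% of those of SPG and 21.2% of those of adult testis. All 3 were at 1 or more at 299 spots, which is 17.0%, 14.7% and 7.08% of the high spots of PGC, SPG and adult testis. A further 432 spots were at 1 or more in PGC and SPG and between -1 and 1 in adult testis. The high spots that lay between -1 and 1 in both other samples numbered 629 in PGC, 786 in SPG and 3410 in adult testis. With an equal spread, all 3 samples shared 951 low and 317 high spots. The low spots then numbered 3526 in PGC, 2784 in SPG and 2590 in adult testis, so the shared part was largest in adult testis and no longer smallest.

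In pairs, PGC and SPG shared 794 high and 1333 low spots, where independent lists of these sizes would share 91.6 and 124. With an equal spread PGC and SPG shared 1410 high and 1970 low spots, from longer lists. SPG and adult testis shared 569 high and 1441 low spots (221 and 258 for independent lists), and PGC and adult testis shared 465 and 1680 (191 and 301). Simulated unchanged samples with a common control shared no spot at this threshold with the noise of row 30, and at most 1 spot per pair and side with the central spread as noise. The simulated noise of PGC and SPG seldom reached 1, so these low numbers were largely set by the assumed SD. The simulation leaves out real effects and the independent lists leave out the shared control, so the excess over either is not a measure of a shared effect, and part of it may come from the control. Opposite sides were taken at 54 spots by PGC and SPG, at 288 by SPG and adult testis, and at 272 by PGC and adult testis. The first of these counts was 119 with an equal spread.

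Across spots, which are not independent replicates, PGC and SPG had a Pearson r of 0.67 (95% interval over blocks 0.66 to 0.68) and a Spearman rho of 0.51. For PGC and adult testis r was 0.38 (0.36 to 0.39) and rho 0.30, and for SPG and adult testis r was 0.34 (0.32 to 0.35) and rho 0.26. Unchanged samples sharing a control gave simulated r values of 0.50, 0.49 and 0.50 in the same order. These follow from the equal variance assumed for sample and control and not from the data, so they are no baseline for the observed r. The covariances were 0.286 for PGC and SPG, 0.283 for PGC and adult testis and 0.242 for SPG and adult testis, against simulated covariances of 0.0067, 0.0093 and 0.0082. With the central spread as noise, the simulated covariances were 0.029, 0.053 and 0.060. Their size and order follow from the SD assumed for each column. Spots below 0 in both samples gave 0.189, 0.249 and 0.215 of the observed covariances, and spots above 0 in both gave 0.123, 0.114 and 0.119. Spots of opposite sign took away from them, with -0.026, -0.079 and -0.091. The covariances depend on the scale of the columns and on extreme spots. In the same order they were 0.497, 0.268 and 0.203 with an equal spread, and 0.195, 0.184 and 0.151 without the 1% most extreme spots.

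**Figure D2:**
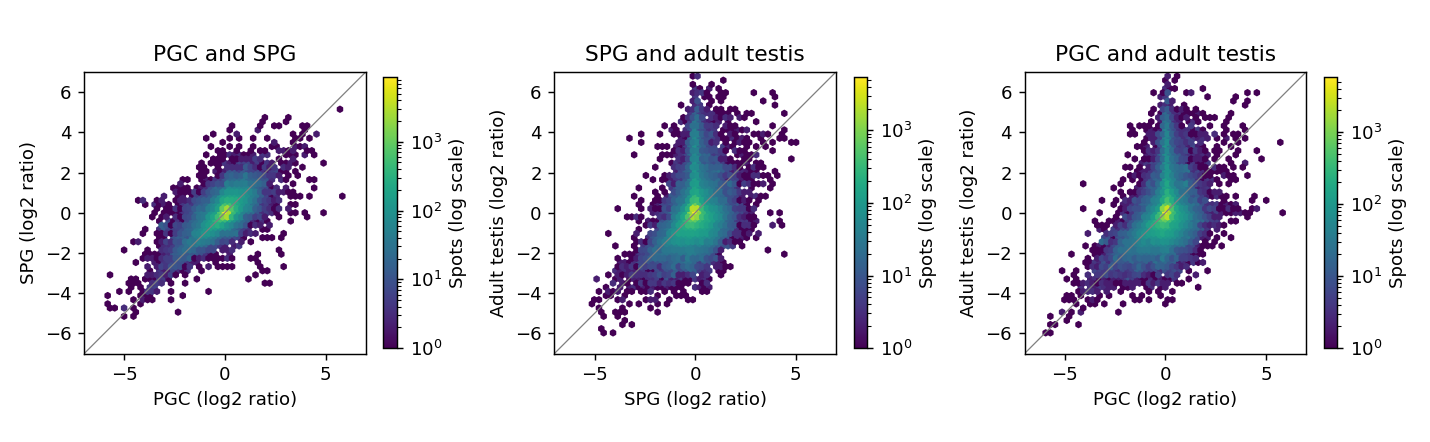
Log2 ratios to gonad-less embryo of each pair of samples, with the colour giving the number of spots per hexagon on a log scale and the grey line marking equal ratios. PGC and SPG lie along the line (r = 0.67), while many spots high in adult testis lie near 0 in PGC and SPG (r = 0.38 and 0.34).

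The difference between the fetal and the postnatal germ cells was the smallest of the 3 indirect comparisons. PGC was at least 1 above SPG at 945 spots and at least 1 below at 1608, together 6.57% of spots, and the SD of the difference was 0.53. With the columns scaled to an equal spread these counts were 1795 and 2564, but the common reference then no longer cancels. The 2 highest differences in favour of PGC, at spots 16_1_1 and 25_1_1, were 5.68 and 5.64, and the 2 lowest, at 13_8_1 and 14_20_1, were -4.81 and -4.74. All of these 4 spots have a row number of 1, as do 12 of the 29 spots with a difference of 3 or more and 12 of the 63 with -3 or less. An even spread over positions would place 0.97 and 2.1 there. Outside rows 1, 29 and 30, a choice made after the values were seen, the highest differences were at 43_5_16 (5.07) and 48_6_12 (4.83). Spot 48_6_12 had 4.90 in PGC, 0.07 in SPG and 2.66 in adult testis. The lowest were at 14_10_24 (-4.53) and 47_18_21 (-4.40), where SPG had 3.71 and 3.84 and adult testis 1.36 and 1.37.

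Both germ cell samples lay 1 or more away from adult testis at over 3 times as many spots in the deposited values. With an equal spread the counts were 4216 above and 3549 below for SPG, and 4006 and 4293 for PGC. The common reference does not cancel in these scaled differences, so part of them can come from the scaling. For example, spot 8_26_23 had -5.87 in PGC and -5.96 in adult testis as deposited, and -8.22 and -4.03 with an equal spread. SPG was at least 1 above adult testis at 5008 spots and at least 1 below at 3951, 23.0% of spots. Differences of -3 or less were found at 998 spots and of 3 or more at 180. The highest differences in favour of SPG were at 23_15_9 (6.56), with 4.42 in SPG, 1.88 in PGC and -2.13 in adult testis, and at 16_21_16 (5.45). The lowest were at 47_1_1 (-6.95), which is the first spot of its block, and at 47_15_18 (-6.88). PGC was at least 1 above adult testis at 4501 spots and at least 1 below at 4107, 22.1% of spots, and with median centring the larger side turned, to 4148 above and 4339 below. There were 971 spots at -3 or less and 191 at 3 or more. The highest differences in favour of PGC were at 43_5_16 (5.79) and 22_11_19 (5.43), and the latter had 1.62 in PGC, -2.44 in SPG and -3.81 in adult testis. The lowest were at 9_19_8 (-6.71) and 2_25_10 (-6.69), which had ratios of 0.03 and 0.01 in PGC and of 0.08 and 0.09 in SPG.

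The share of spots beyond 1 differed by row. In PGC it was 18.2% in row 1, between 10.4% and 12.8% in rows 2 to 24, between 5.79% and 7.33% in rows 25 to 28, 1.62% in row 29 and 0.08% in row 30. In SPG it was 12.5% in row 1 and between 6.94% and 9.34% in rows 25 to 28, where rows 2 to 24 had 9.72% to 13.7%. In adult testis it was 36.1% in row 1 and between 16.4% and 21.5% in rows 25 to 28, where rows 2 to 24 had 24.0% to 27.9%. The mean ratio differed little by position: blocks accounted for 0.19% of the variance in PGC, 0.47% in SPG and 0.51% in adult testis, and the row number for 0.52%, 0.43% and 0.69%.

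**Figure D3:**
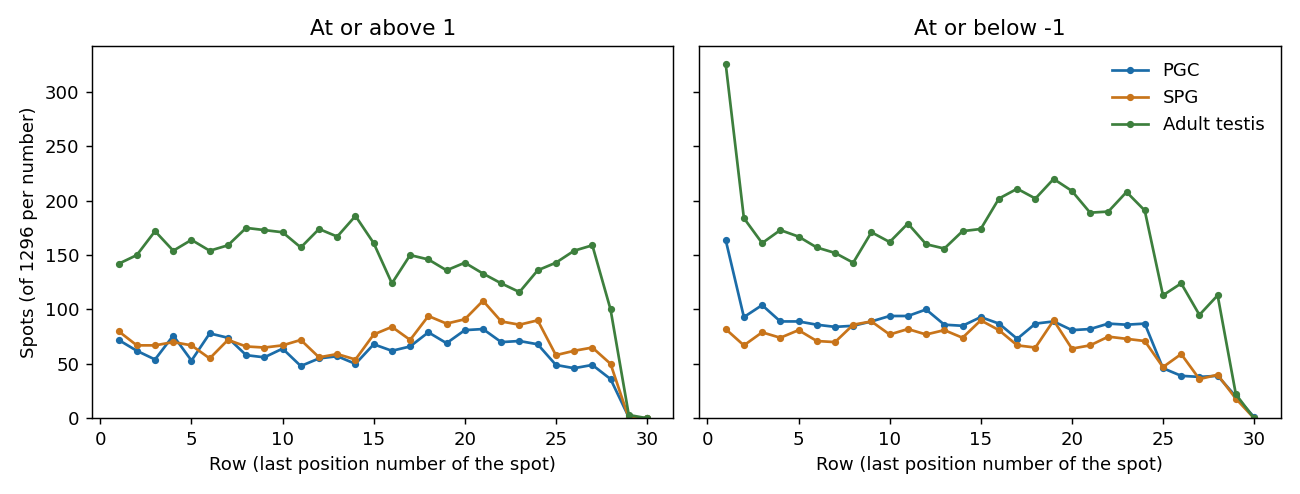
Number of spots at a log2 ratio of 1 or above (left) and of -1 or below (right) by the row number (the last position number), for PGC, SPG and adult testis, out of 1296 spots per number. Row 30 holds 1 low spot in PGC and no other spot beyond 1, and row 1 holds 164 low spots in PGC, 82 in SPG and 326 in adult testis.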

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

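The tests of centring and of the ratio of the tails, of a shared component and of the larger testis variance, and of repeated probes in row 1, were chosen after the result was seen, and the settings by position were added after the data were examined.

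Spots on opposite sides of the embryo level drew attention because the single sample of one group lay at 1 or above and that of the other at -1 or below; the differences were not tested. There were 54 such spots for PGC and SPG, 288 for SPG and adult testis and 272 for PGC and adult testis, where independent lists of the same sizes would give 216, 478 and 481. With the columns scaled to an equal spread, the 3 counts were 119, 204 and 232. The lists then have other sizes, so the numbers for independent lists do not apply to these 3 counts. Of the 288, 231 were high in SPG and low in adult testis, and of the 272, 218 were high in PGC and low in adult testis. Independent lists would give 257 and 222 in these directions. In the reverse directions there were 57 and 54 spots, where independent lists would give 221 and 258. Independent lists leave out the shared control.

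The first pattern weighed is the high side of adult testis, whose 1099 spots at 3 or above are 16.4 times the larger of the counts in PGC and SPG. Offsets of the columns and rows were too small to make this ratio. The column medians were 0.05 in PGC, 0.00 in SPG and -0.02 in adult testis, and the ratio is 17.6 after median centring. The row medians of adult testis ran from -0.09 to 0.11, and the ratio is 17.5 after centring by row without rows 1, 29 and 30. With offsets this small the outcomes of centring were nearly fixed beforehand. A spread that differs by position was not tested. A wider scale of the whole testis column stays open for the number of spots, because with equal spread the counts were 237 in adult testis and 181 in PGC, a ratio of 1.31 (21 and 572 at -3 or below); equal scaling also removes a real, broad difference. It does not account for the asymmetry: the 99th percentile was 1.46 times the size of the 1st percentile in adult testis and 0.70 and 0.91 times in PGC and SPG, which no scale factor changes. That whole adult testis holds transcripts of later germ cell stages that the embryo lacks is a hypothesis that these spots without gene names left untested.

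The second pattern is the stronger correlation of PGC with SPG than of either with adult testis. If a single component carried equally by all 3 columns were all that they shared, the covariances would be equal. That of PGC with SPG exceeded that of SPG with adult testis by 0.044 (95% interval over blocks 0.034 to 0.053). This argues against an equal component as all that the columns share. An equal component beside other shared parts stays open. The common embryo reference need not be carried equally where the columns differ in scale. Simulated with the central spread as noise, it gave covariances of 0.029 for PGC and SPG, 0.053 for PGC and adult testis and 0.060 for SPG and adult testis. The simulation scaled the control to the SD of each column, so these unequal values were set by that choice. Its part in the correlations therefore cannot be told from these values. Rows 1, 29 and 30 and offsets of the blocks do not account for the gap in r. It was 0.32 after block centring without these rows, and 0.30 as deposited. Blocks held only 0.19% of the variance in PGC, 0.47% in SPG and 0.51% in adult testis, so block centring by itself could change r little. The larger variance of the testis column cannot be told apart from a closer relation of PGC to SPG: the covariance of PGC with SPG exceeded that of PGC with testis by only 0.0029 over all spots (-0.0093 to 0.014), but by 0.018 (0.0053 to 0.030) without rows 1, 29 and 30, and the covariances, being on the deposited scale, were 0.497 and 0.268 with an equal spread. A nearer stage of the germ line in PGC and SPG stays open and untested.

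The third pattern is the place of the largest differences between PGC and SPG. Of 378 spots with a difference of at least 2 either way, 69 had a row number of 1, where an even spread would give 12.6, and 19 of the 69 were the first spot of their block. The other 50, in 33 blocks, all had PGC below SPG, with medians of -3.10 in PGC and -0.67 in SPG. Of these 50, 72% had at least 3 others among them within a distance of 0.25 over the 3 samples. The upper end of the 95% range was 0% over 1000 draws of as many spots with such differences from other positions. The draws were taken from both directions (94 spots above and 215 below), so they were not matched to the 50 in this respect. The 50 spots may be a few probes printed repeatedly, such as control spots. The spots of row 2, taken as the neighbours, had a median difference of 0.20 in size, against 0.19 over all spots. This argues against a local fault that reached row 2. A fault confined to row 1 would leave row 2 unchanged and stays open. No biological explanation was tested for the place of these spots.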

How the results depend on the processing

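Alternatives concerning position were added after the data were examined; the others were fixed before. The named spots and the correlations kept their sign where they were recomputed. The order of the samples by spots beyond 1 changed with equal spread, when adult testis had 2984 high spots and PGC 2992. Median, block and row centring, and leaving out rows 1, 29 and 30, kept all 14 leading counts within 0.89 to 1.12 times their values. Scaling to equal spread moved 4 of the 14 by over 1.5 times: PGC at 1 or above to 2992, adult testis at -1 or below to 2590, and PGC against SPG to 1795 above and 2564 below. In all differences between samples, this scaling leaves part of the common reference in place. Others moved by less, such as PGC at -1 or below to 3526, SPG to 2920 high and 2784 low, and adult testis at 1 or above to 2984. The share of higher spots moved by at most 10 percentage points under rescaling and centring, but the larger side turned in 3 comparisons. PGC against adult testis turned from 4501 above and 4107 below to 4148 and 4339 with median centring, 4072 and 4335 with block centring, 4033 and 4415 with row centring and 4006 and 4293 with equal spread. Adult testis against embryo turned to 2984 above and 2590 below with equal spread. SPG against embryo, nearly even as deposited, turned to 2045 and 2017 with median centring and also with equal spread. It turned as well with block centring (2037 and 2022), with row centring (2040 and 2013) and without rows 1, 29 and 30 (1950 and 1933). A threshold of 1.5 left, for high and low spots, 610 and 1240 in PGC, 732 and 892 in SPG, 2933 and 2506 in adult testis, 300 and 622 for PGC against SPG, 2681 and 2740 for SPG against adult testis and 2328 and 2799 for PGC against adult testis, with 92 high and 472 low in all 3 samples. A threshold of 2 left 234 and 686 in PGC, 277 and 414 in SPG, 2120 and 1290 in adult testis, 112 and 266 for PGC against SPG, 1267 and 1926 for SPG against adult testis, and 1115 and 1896 for PGC against adult testis, with 37 high and 219 low in all 3. A stricter threshold leaves fewer spots by construction, but at 1.5 and 2 the larger side also turned in all 3 comparisons that involve adult testis. Without the most extreme 1% of spots, r was 0.63 for PGC and SPG, 0.32 for PGC and adult testis and 0.27 for SPG and adult testis; without rows 1, 29 and 30, r of PGC and SPG was 0.69; the cause of these shifts and of those with equal spread was not tested. Signal over background is not in the ratio table, so spots near background were not separated from those with a true ratio near 0. No paired analysis was possible because each group has 1 sample. The alternatives that need gene names (the probe with the largest absolute value, list members in no other list, random lists matched on probes, genes with 2 or more probes, named and X-linked genes) were not run, nor was quantile normalization, which was planned for intensities.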

Other observations

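Rows 29 and 30 held fewer spots beyond 1 than the other rows in all 3 samples, and row 1 held more low spots in PGC and adult testis but not in SPG, observations made after the data were examined. At row 30, none of 1296 spots was at 1 or above in any sample, and 1 spot was at -1 or below, in PGC. At row 29, the spots at 1 or above numbered 1 in PGC, 0 in SPG and 3 in adult testis, and those at -1 or below numbered 20, 18 and 22. The 20 low spots of PGC at row 29 all had odd second numbers between 7 and 13, lay in 18 blocks, and had means of -1.65 ± 0.28 in PGC, -1.17 ± 0.17 in SPG and -1.34 ± 0.21 in adult testis (SD over 20 spots). At row 1, 164 spots of PGC and 326 of adult testis were at -1 or below, where rows 2 to 28 had medians of 87 and 172 and highest counts of 104 and 220. In SPG the count there was 82, within the range of 36 to 90 in rows 2 to 28.

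The first spot of each of the 48 blocks varied more than the table as a whole. Its SD over blocks was 1.26 in PGC, 1.46 in SPG and 1.53 in adult testis, against 0.67, 0.64 and 1.13 over all spots. It was at 1 or above in 22 blocks in PGC, in 1 block in SPG and in 12 blocks in adult testis, and at -1 or below in 7, 16 and 6 blocks.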
